A study of Escherichia coli str. K-12 substr. MG1655 with 4 samples.

How the data were processed

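RNA-seq measurements came from 4 chemostat cultures of Escherichia coli K-12 MG1655, the sequenced laboratory reference strain, grown in M9 minimal medium. Per the labels' protocols, chemostat samples were collected at steady state into an RNA-stabilising reagent, RNA was purified on columns and treated with DNase, ribosomal RNA was depleted, and strand-marked libraries were made by a modified dUTP method. A chemostat holds a culture at a set growth rate by feeding medium at a set dilution rate, and the nutrient in shortest supply limits growth. Glucose or ammonium was limiting, each at growth rates of 0.3 and 0.44 per h, which gives 4 conditions with 1 library each. Samples were placed in conditions by the labels for growth limitation and growth rate. The column header of the glucose-limited file labelled 0.3 per h reads C_031, and the label was followed.

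The values in the files are FPKM, fragment counts normalised for gene length and for the mapped fragments of the library, made by the authors with Bowtie and Cufflinks 2.0.2, per the submitters' processing notes. The version of Bowtie is not given in the sources used here, and neither is the way fragments that match several places were handled. Each deposited FPKM comes with a lower and an upper bound in FPKM, and each file lists the same 4380 features with their lengths. The deposited bounds were not used, because between 639 and 947 features per library had a value above their own upper bound. The files name the MG1655 chromosome without a version, so no coordinates are given. Gene symbols were taken from a RefSeq gene table of assembly ASM584v2 by locus tag, which matched 4299 of the 4380 features. Features without a match keep the identifier in the files. Listed rRNA and tRNA features numbered 0.

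Sequencing depth was read from the steps between low FPKM values. For genes of at least 600 nt, values were whole multiples, within 0.1 of a fragment, of the FPKM of 1 fragment once a mean fragment length was taken off the gene length. Genes held out of this estimation came out whole in 99.3% to 100% of cases. It gave 4173000 fragments of mean length 220.5 nt for glucose limitation at 0.3 per h, and 5083000 of 211.5 nt for glucose limitation at 0.44 per h. The ammonium-limited libraries had 5400000 fragments of 264.0 nt at 0.3 per h and 5835000 of 273.5 nt at 0.44 per h. In a gene of 1000 nt, 1 fragment was worth 0.236 to 0.308 FPKM. Intervals given for ratios are exact 95% binomial intervals on these recovered fragments. They are for the ratio of scaled FPKM without the added 1 described below, so for low genes they are not centred on the log2 changes and folds printed. They cover counting error only, since amplified copies of a fragment are not independent molecules and no culture was repeated.

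FPKM values were divided by median-of-ratios factors, taken over features at 10 FPKM or more in all 4 libraries, which were 0.908, 1.06, 0.961 and 1.08 for glucose at 0.3, ammonium at 0.3, glucose at 0.44 and ammonium at 0.44 per h. Features with a mean scaled FPKM of at least 10 were tested, which left 3297. Changes are on the log2(scaled FPKM + 1) scale, which understates the change of low genes. The additive model with limitation and growth rate as terms was fitted with limma 3.58.1 in R 4.3.3, with a variance trend and Benjamini-Hochberg adjustment over all features tested, and a threshold of 0.05 on the adjusted p. It leaves 1 residual degree of freedom per gene, so the p-value of a gene measures its change against its own departure from additivity and that of other genes, not against replicate cultures. The single contrasts (ammonium over glucose at each rate, 0.44 over 0.3 per h under each limitation) and the difference of growth-rate effects have no test.

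Tested on simulated data with the real means, the limitation test on 3297 genes recovered 2% of genes changed by 1 log2 unit, 26% at 2 units, 82% at 4 units and 98% at 8 units, with 3 false calls. The growth-rate test gave 1 false call. These figures describe the simulated data only, and whether they hold for the real libraries was not tested. In the real libraries the residual is the departure from additivity. Its spread over genes (SD of the log2 contrast) was 0.833, against 0.888 for growth rate. Fixed before the data were examined were the model, the thresholds, 31 gene lists covering 603 genes (598 found in the files), most processing alternatives and the rule for naming genes. For each main effect the rule takes up to 12 genes per direction with the largest called change of the same sign in both contrasts, and fills empty places, as values only, by the larger minimum of both ratios. From each list it takes up to 4 members with the largest change in the contrast described, and for the difference of growth-rate effects the 5 largest in each direction. Features under 150 nt are not named under the first and last part. Where a gene outside the rule is named, the text says that it was chosen after its values were seen. For each list, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these libraries and is not a test. Members of an operon are transcribed together and are not independent.

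The alternatives fixed in this way were pseudocounts of 0.1 and 10, no filter or a minimum of 50 scaled FPKM, FPKM as deposited, rescaling of each library to a fixed sum (TPM), quantile normalization, no variance trend, the other factor left out of the model, and each library left out in turn. Restriction to genes of at least 300 nt, removal of repeated features, and robust variance estimation were chosen after seeing the data. Repeated features were taken as insertion-sequence genes, tufA, tufB and every feature without a symbol, whether or not it is known to be repeated. That removal also took out b1016. Figures were drawn with matplotlib 3.10.9, and depth was estimated in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.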

Results

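Transcript levels were compared between 4 steady-state chemostat cultures, glucose-limited or ammonium-limited, each at 0.3 and 0.44 per h. The series asks how nitrogen-limited and carbon-limited growth differ at 2 growth rates. Each condition has 1 library, so no difference reported here has a replicate check. Mean fragment length split by limitation (220.5 and 211.5 nt under glucose, 264.0 and 273.5 nt under ammonium limitation), and the labels give no preparation batch, so a batch that followed limitation and limitation itself cannot be told apart. Recovered depth ranged from 4173000 to 5835000 fragments per library, and all 4 libraries list 4380 features, of which 321 to 344 per library are listed at 0. The small stable RNAs ssrA (tmRNA), ssrS (6S RNA) and rnpB (the RNA of RNase P) together made up 56.1% of the summed FPKM in glucose limitation at 0.3 per h, 47.6% in glucose limitation at 0.44 per h, 45.1% in ammonium limitation at 0.3 per h and 37.0% in ammonium limitation at 0.44 per h. At 183 nt, ssrS is shorter than the mean fragment of all 4 libraries, so its FPKM and these shares are uncertain. Values below are scaled FPKM.

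The genes zinT, znuA, ykgM and pliG were far lower under ammonium than under glucose limitation at both growth rates. The zinc-binding protein gene zinT (b1973) had 12486 and 12049 scaled FPKM in the glucose-limited libraries at 0.3 and 0.44 per h, and 5.86 and 6.73 in the ammonium-limited ones. The gene of the periplasmic zinc-binding protein of the ZnuABC transporter, znuA (b1857), had 6652 and 6517 under glucose limitation and 98.3 and 104 under ammonium limitation. The gene ykgM (b0296), which encodes an alternative ribosomal protein L31 without the zinc-binding motif, had 8463 and 11958 against 7.19 and 7.54, and is 264 nt long, no longer than the mean fragment of the ammonium-limited libraries. The lysozyme inhibitor gene pliG (b1178) had 2286 and 2417 against 134 and 142. In the opposite direction, tufB (b3980), 1 of the 2 copies of the elongation factor Tu gene, had 522 and 641 under glucose limitation and 10785 and 12532 under ammonium limitation.

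All 5 passed the limma test across both growth rates. On the log2 scale zinT fell by 10.72 (SE 0.173, adjusted p = 0.0089), ykgM fell by 10.23 (SE 0.205, adjusted p = 0.013), znuA fell by 6.01 (SE 0.155, adjusted p = 0.018) and pliG fell by 4.08 (SE 0.155, adjusted p = 0.029). The change in tufB was 4.33 (SE 0.144, adjusted p = 0.024). Recovered fragments for zinT numbered 20357 and 25876 under glucose limitation and 13 and 16 under ammonium limitation, and the counting interval of its log2 ratio ran from -11.97 to -10.28 at 0.3 per h and from -11.61 to -10.11 at 0.44 per h. The tufA copy (20066 and 23868 under glucose, 10947 and 13458 under ammonium limitation) is nearly identical in sequence to tufB, and the sum of both copies had a mean log2 ratio of 0.08, so the value of either copy is uncertain.

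In all, 17 of 3297 tested features changed with limitation, 3 higher and 14 lower under ammonium, and 319 had an unadjusted p under 0.05 where 165 were expected by chance. Among the 17, 10 were shorter than 150 nt, and 11 were listed at 0 in both libraries of a limitation. Beyond the genes above, the rule named dinQ (b4613), a small toxin gene at 594 and 799 scaled FPKM under glucose limitation, and yciX (b4523) at 623 and 658. Both are listed at 0 in both ammonium-limited libraries, and neither passed when the minimum was set at 50 scaled FPKM. The other 10 called features were named after their values were seen. Listed at 0 under ammonium limitation were rybA, sra, ryjA, pyrL, ykgO, fnrS, sibB and mgtS, all under 150 nt, and all 23 features with this pattern were shorter than the mean fragment of either ammonium-limited library. The small RNA ryhB, which represses iron-using proteins when iron is scarce, rose to 78591 and 97607 under ammonium from 6310 and 7671 under glucose limitation (log2 change 3.65, SE 0.127, adjusted p = 0.024 in limma). At 90 nt it is shorter than the mean fragment of all 4 libraries, and it did not pass under quantile normalization. With no variance trend pliG, tufB, ryhB, sibB and mgtS did not pass. The 111 nt feature b1016 was listed at 0 under glucose limitation and had 21420 and 25198 under ammonium limitation. Calls numbered 307 (154 higher, 153 lower) under TPM rescaling and 6 when features under 300 nt were left out. When single libraries were left out, the calls depended strongly on which library it was.

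Places that calls did not fill went to features that cannot be given a fold. On the higher side under ammonium these were insH9, insH4, insC1, insC5, insC6, insE1, insE3 and insD7, all genes of insertion sequences, and 3 features without a symbol. All 11 are listed at 0 in both glucose-limited libraries, with insH9 at 218 and 262 and insH4 at 207 and 245 scaled FPKM under ammonium limitation. On the lower side were mokB, yhfG, hokB, gnsA, marB and bcsF, all listed at 0 in both ammonium-limited libraries. Of these, hokB had 1336 and 178 scaled FPKM and mokB had 997 and 271 under glucose limitation. Outside the rule, and chosen after their values were seen, the znu neighbours were also lower under ammonium limitation in these libraries. The permease gene znuB had 274 and 292 against 42.8 and 40.9, the ATPase gene znuC had 521 and 403 against 78.7 and 75.7, and the adjacent endopeptidase gene mepM had 1012 and 850 against 96.0 and 88.3. Their adjusted p in limma were 0.098, 0.12 and 0.054.

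Iron uptake genes were higher under ammonium limitation throughout. All 29 tested members were higher under ammonium than under glucose limitation at both rates, with a median log2 ratio of 1.24 at 0.3 per h and 1.64 at 0.44 per h, both above all matched random lists (percentile 100). Over all genes tested 0 of the 29 passed, while adjusted over the list alone 22 rose, 0 fell and 7 did not pass. The enterobactin synthesis gene entE (b0594) had 17.1 and 15.4 scaled FPKM under glucose limitation and 136 and 354 under ammonium limitation. The values of entC (b0593) were 35.4 and 32.5 against 213 and 484. For the siderophore receptor genes, cirA (b2155), which did not pass, had 57.4 and 28.4 against 124 and 872, and fiu (b0805) had 16.8 and 15.8 against 81.0 and 393.

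**Figure D1:**
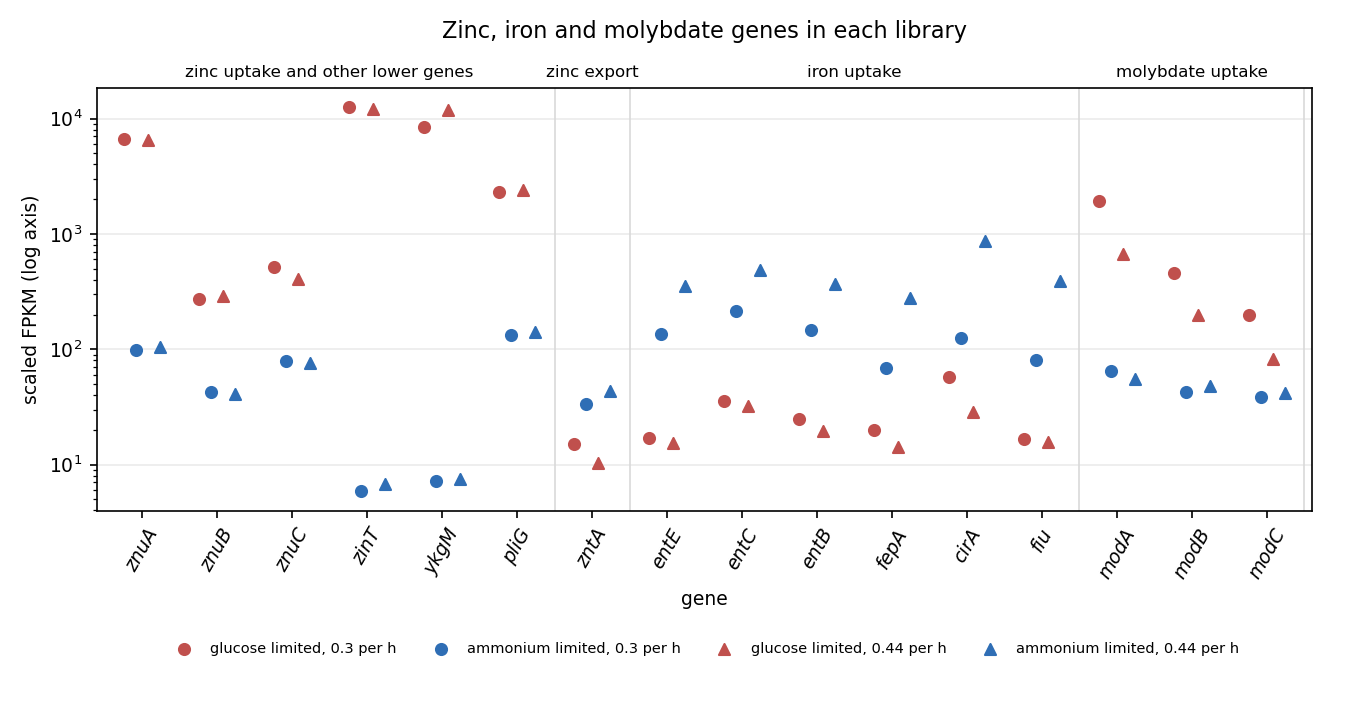
Scaled FPKM (log axis) of genes for zinc, iron and molybdate in each of the 4 libraries, 1 point per library (circles 0.3 per h, triangles 0.44 per h, red glucose-limited, blue ammonium-limited). The points of znuA lie at 6652 and 6517 under glucose and at 98.3 and 104 under ammonium limitation, and those of entE at 17.1 and 15.4 against 136 and 354.

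At 0.3 per h, the ammonium-limited culture had far lower levels of genes for the uptake and use of other carbon sources. The list of carbon-source uptake genes that depend on CRP-cAMP, the regulator active when sugar is scarce, had a median log2 ratio of -3.08, with 43 of 44 tested members lower and 36 lower by at least 2-fold. Within it, the maltose porin gene lamB (b4036) had 2131 under glucose and 9.71 under ammonium limitation, 199-fold lower, and the maltose-binding protein gene malE (b4034) had 2229 against 17.5, 121-fold lower. The tryptophanase gene tnaA (b3708) had 403 against 2.57. The acetyl-CoA synthetase gene acs (b4069) was 31.1-fold lower at 2403 against 76.2, and its operon partners yjcH and the acetate permease gene actP were 55.5-fold and 65.4-fold lower. Fatty acid degradation genes had a median of -2.96 with 9 of 9 lower, among them fadB at 318 against 20.9. Genes of the TCA cycle had a median of -1.65 with 15 of 15 lower, among them the succinate dehydrogenase genes sdhC (2586 against 328) and sdhD (2668 against 288). The percentiles of these 3 lists, and of the list for acetate uptake, glyoxylate shunt and gluconeogenesis (median -1.79), among matched random lists were 0.

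Most members of the RpoS general stress and Ntr lists had higher values in the same library, and 0 members of either passed the limma test for limitation. The RpoS general stress list had a median of 1.21 (percentile 100), with 29 of 32 members higher. The glutamate decarboxylase genes gadA (b3517) and gadB (b1493) had 5072 and 5062 scaled FPKM in the ammonium-limited culture and 171 and 193 in the glucose-limited culture, 29.4-fold and 26.1-fold higher. The glutamate antiporter gene gadC was 22.9-fold higher. Of the 42 Ntr genes, the set that the nitrogen regulator NtrC and its partner Nac serve, 38 were higher with a median of 1.03 (percentile 100). The PII-like regulator gene glnK (b0450) had 2509 against 444, and rutF and rutG, of the pyrimidine degradation operon, had 420 against 103 and 214 against 52.2. The curli list, whose products form adhesive fibres, had a median of 1.31 with csgE at 97.4 against 4.65. Respiratory lists were lower under ammonium limitation at this rate, with medians of -1.02 for ATP synthase (8 of 8 lower) and -0.67 for NADH dehydrogenase I (12 of 13 lower). The counting interval of the log2 ratio of gadA ran from 4.78 to 4.99, and that of malE from -7.30 to -6.70.

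At 0.44 per h most of these ratios were smaller or of the other sign. The carbon-source uptake list had a median log2 ratio of -0.37 with 32 of 44 members lower, and lamB was 3.86-fold lower under ammonium limitation. The medians were -0.60 for fatty acid degradation, -0.28 for the TCA cycle and -0.10 for acetate uptake, glyoxylate shunt and gluconeogenesis. The sign of the last turns positive under FPKM as deposited (0.07) and under TPM rescaling (0.05). Medians were 0.11 for NADH dehydrogenase I (8 of 13 higher), -0.11 for ATP synthase (8 of 8 lower) and -0.15 for curli (5 of 5 lower), the last 2 turning positive under FPKM as deposited and under TPM rescaling. The RpoS list had a median of -0.48 (percentile 0) with 21 of 32 members lower, among them gadA at 1349 under glucose and 388 under ammonium limitation. The Ntr list had a median of -0.20 (percentile 0.05) with 31 of 42 members lower. The values of glnK were 937 and 923, and rutC and rutE of the pyrimidine operon had 98.7 against 29.6 and 70.6 against 23.0. Across 3297 genes, the log2 ratios of limitation at the 2 rates, which share no library, had Pearson's r = 0.438 and Spearman's rho = 0.370; genes are not independent replicates. At least 2-fold higher under ammonium were 261 genes at 0.3 per h and 158 at 0.44 per h, 79 of them at both. At least 2-fold lower were 429 and 189, 96 of them at both, while 42 differed by at least 2-fold in opposite directions. These counts include short features listed at 0. Among 2981 genes of at least 300 nt, 205 and 116 were higher (62 at both) and 333 and 102 lower (55 at both). Of these longer genes, 23 differed in opposite directions.

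**Figure D2:**
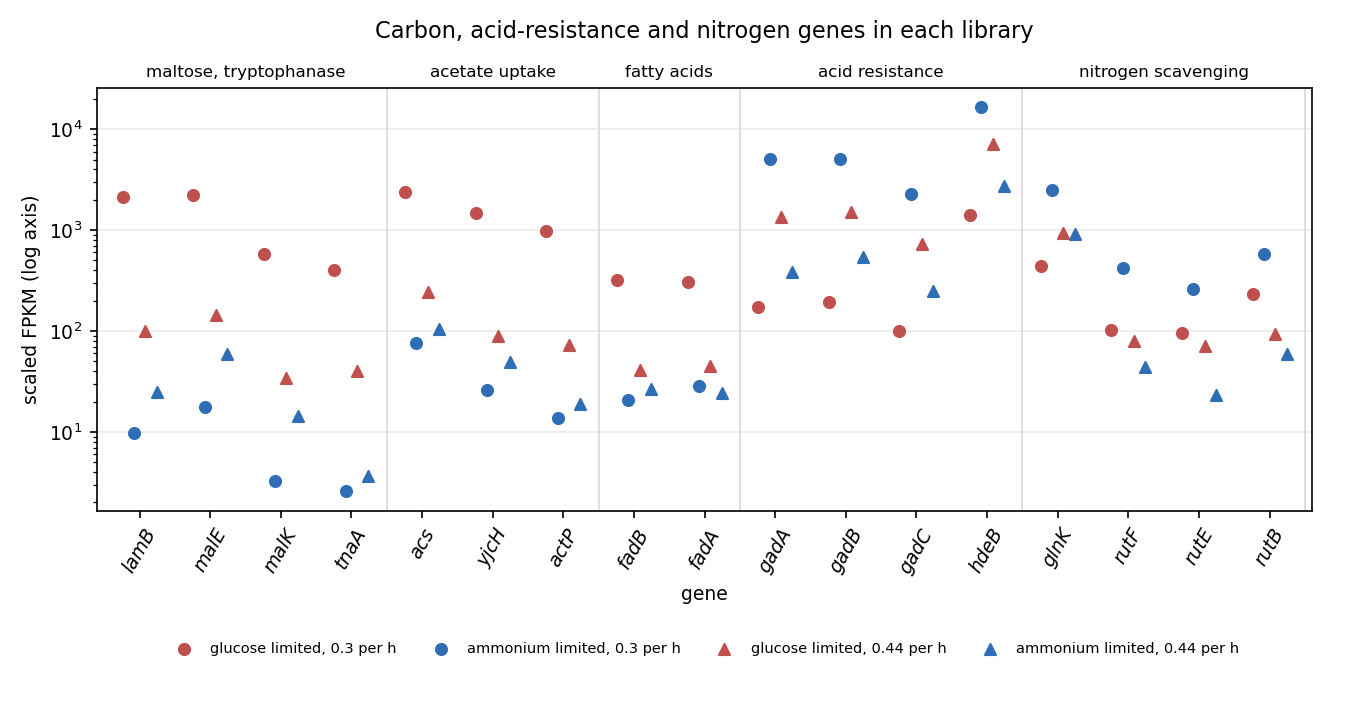
Scaled FPKM (log axis) of genes for carbon-source use, acid resistance (members of the RpoS list) and nitrogen scavenging in each of the 4 libraries, 1 point per library (circles 0.3 per h, triangles 0.44 per h, red glucose-limited, blue ammonium-limited). Glucose limitation at 0.3 per h has the highest points for lamB (2131) and acs (2403), and ammonium limitation at 0.3 per h those for gadA (5072) and glnK (2509).

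For the other lists, medians of the log2 ratio at 0.3 and 0.44 per h were -0.09 and -0.03 for ribosomal proteins, 0.09 and 0.02 for translation factors, 0.07 and 0.08 for aminoacyl-tRNA synthetases, 0.38 and 0.12 for glycolysis and glucose phosphotransferase, and 0.05 and -0.08 for glutamate synthesis and nitrogen sensing. The ribosomal protein medians are positive under FPKM as deposited, TPM rescaling and quantile normalization. For biosynthesis they were 0.40 and 0.28 for arginine and carbamoyl phosphate, 0.31 and 0.15 for branched-chain amino acids, 0.08 and 0.22 for methionine, 0.27 and 0.15 for sulfate assimilation and cysteine, 0.09 and 0.09 for histidine and aromatic amino acids, 0.28 and 0.12 for other amino acids, and 0.52 and 0.16 for purines and pyrimidines. They were -0.42 and 0.20 for flagella and chemotaxis (19 of 47 genes tested), -0.33 and -0.10 for cytochrome oxidases, -0.45 and -0.38 for anaerobic respiration and fermentation, -0.18 and 0.19 for outer membrane porins, -0.25 and -0.12 for heat shock and proteolysis, -0.32 and -0.16 for phosphate starvation, 0.15 and -0.30 for glycogen metabolism, and -0.03 and -0.39 for cell envelope stress and colanic acid. Under TPM rescaling the medians at 0.3 per h turn positive for flagella, cytochrome oxidases, anaerobic respiration, porins, heat shock, phosphate starvation and envelope stress (those of porins and envelope stress also under FPKM as deposited and quantile normalization). At 0.44 per h those for glutamate synthesis, cytochrome oxidases and heat shock turn positive under TPM rescaling and FPKM as deposited, and that for phosphate starvation under FPKM as deposited. Over all genes tested 1 translation factor passed as higher (tufB, whose value is uncertain because of tufA), 1 ribosome hibernation factor fell (sra, listed at 0 under ammonium limitation) and 0 members of the other 29 lists passed. Adjusted over the list alone, tufB and the initiation factor gene infA (1052 and 1992 under glucose, 2978 and 5010 under ammonium limitation, and at 219 nt shorter than the mean fragment of the ammonium-limited libraries) passed as higher, tufA passed as lower, with the same doubt for both tuf copies, and 10 translation factors did not pass. The 4 hibernation factors had medians of -1.72 and -1.34, and raiA had 4965 and 1033 under glucose and 574 and 435 under ammonium limitation, and hpf had 1167 and 1408 against 2135 and 1872.

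**Figure D3:**
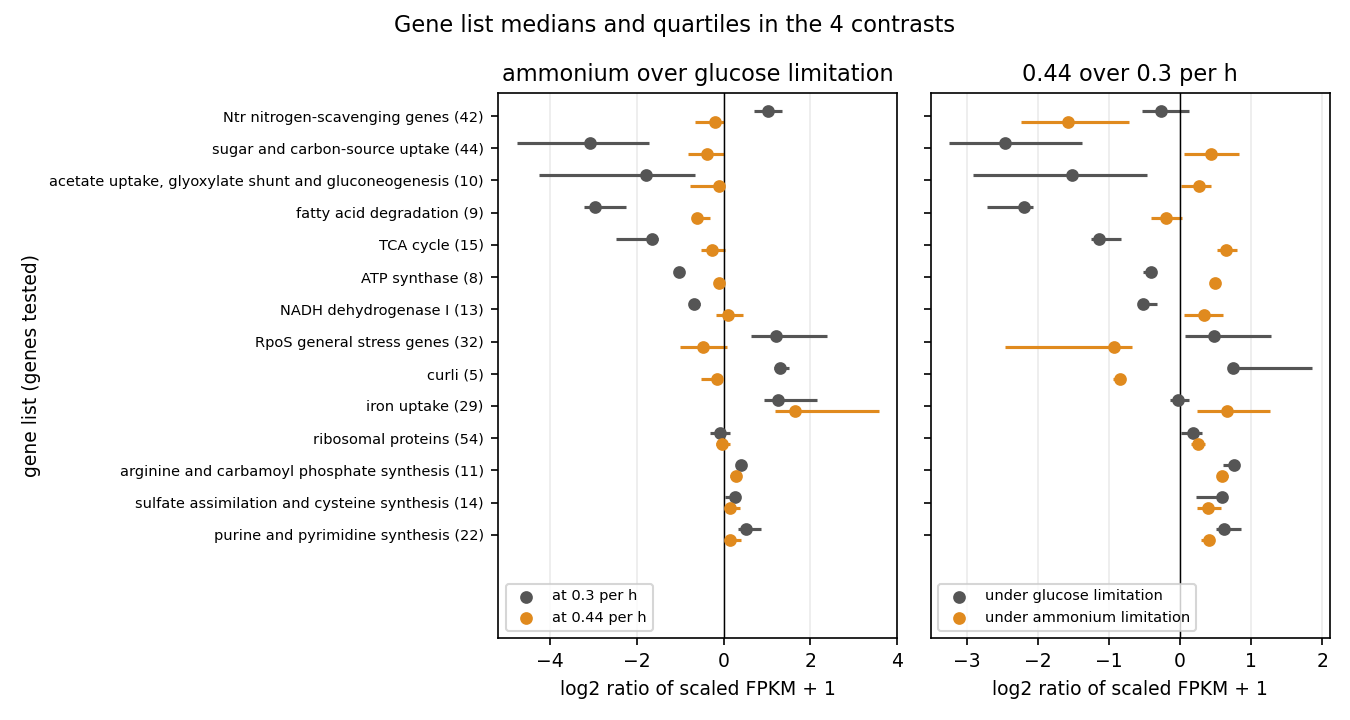
Median (point) and quartiles (line) of the log2 ratio of scaled FPKM + 1 over the tested members of 14 gene lists, for ammonium over glucose limitation at each growth rate (left) and for 0.44 over 0.3 per h under each limitation (right). Carbon-source uptake lies at -3.08 and -0.37 on the left and at -2.46 and 0.43 on the right, and iron uptake at 1.24 and 1.64 on the left.

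Growth rate was compared next, 0.44 against 0.3 per h within each limitation. At the faster rate gltB, gltD, asnA and cysC had higher values and ydcS, ydcT and ydcV lower values under both limitations. The glutamate synthase genes gltB (b3212) and gltD (b3213) had 1425 and 1406 at 0.3 per h and 2696 and 2578 at 0.44 per h under glucose limitation, and 1380 and 1309 against 2691 and 2479 under ammonium limitation. The asparagine synthetase gene asnA (b3744) had 75.6 and 35.4 at 0.3 per h and 174 and 339 at 0.44 per h under glucose and ammonium limitation. The adenylylsulfate kinase gene cysC (b2750) had 101 and 191 against 234 and 499. Lower at the faster rate under both limitations were ydcS (b1440), of a putative ABC transporter, at 516 and 433 against 98.3 and 50.4, and its neighbours ydcT (152 and 183 against 37.2 and 25.1) and ydcV (45.1 and 60.1 against 14.7 and 9.74).

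No gene passed the limma test for growth rate over all 3297 tested (smallest adjusted p = 0.83), and 158 had an unadjusted p under 0.05 where 165 were expected by chance. Under TPM rescaling 96 passed (41 higher, 55 lower). Adjusted over the list alone, 10 of 11 arginine and carbamoyl phosphate genes rose, 0 fell and 1 did not pass, with medians of 0.75 under glucose and 0.58 under ammonium limitation. Examples are argG (b3172), argininosuccinate synthase, at 708 and 745 against 1197 and 1317, and carA at 769 and 1086 against 1513 and 1616. In the list for glutamate synthesis and nitrogen sensing, gltB (log2 change 0.94, SE 0.145) and gltD (0.90, SE 0.146) rose adjusted over the list alone and the other 4 did not pass. The remaining 29 lists had 0 members passing. Purine and pyrimidine synthesis genes had medians of 0.61 and 0.40 (20 and 22 of 22 members higher), with the IMP dehydrogenase gene guaB (b2508) at 246 and 879 against 736 and 1441. Sulfate assimilation and cysteine genes had 0.59 and 0.39 (13 of 14 higher in each), other amino acids 0.39 and 0.22, ribosomal proteins 0.18 and 0.25 with 43 and 48 of 54 members higher, and aminoacyl-tRNA synthetases 0.23 and 0.18 with 21 of 22 higher in each. Percentiles among matched random lists were 100 and 99.99 for purines and pyrimidines, 99.99 and 99.88 for sulfate and cysteine, and 99.96 and 95.23 for other amino acids. They were 94.6 and 97.4 for ribosomal proteins and 95.8 and 88.6 for aminoacyl-tRNA synthetases, all inside the central 95% of random lists. Medians for anaerobic respiration and fermentation were -0.53 and -0.37.

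The remaining genes that the rule named for growth rate are reported as values. At the faster rate, folB (22.9 and 17.6 against 58.0 and 45.4 for glucose and ammonium limitation), yghG (4.15 and 8.19 against 16.4 and 23.7), ymdA (5.49 and 8.95 against 19.7 and 24.1), yacG (59.4 and 337 against 273 and 874) and arfA (11.1 and 31.0 against 37.3 and 138) were higher in these libraries. The copper efflux genes cusC (12.1 and 152 against 1.06 and 3.03) and cusB (10.5 and 102 against 3.23 and 7.68) were lower, as were the propionate gene prpB (34.7 and 22.0 against 6.63 and 1.80) and yqeC (76.8 and 25.1 against 9.51 and 5.43). Features with a value of 0 in at least 1 library were renD, ydfC, mokC, alpA and azuR among those higher and yqaE, ygeI, rem, yhjR and hypC among those lower. Of these, renD, ydfC, mokC and alpA are listed at 0 in both libraries at 0.3 per h, and yqaE and ygeI in both at 0.44 per h.

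Under glucose limitation the faster rate came with lower levels of the carbon-source lists, and under ammonium limitation with lower levels of the nitrogen and stress lists. These ratios are not independent of the limitation ratios at 0.3 per h. The single glucose-limited library at 0.3 per h enters both ratios for the carbon-source lists. For the nitrogen and stress lists, the single ammonium-limited library at 0.3 per h does. The carbon-source uptake list had a median log2 ratio of -2.46 under glucose limitation, with 43 of 44 members lower, and 0.43 under ammonium limitation, with 34 of 44 higher. The values of malE went from 2229 to 143 under glucose limitation and from 17.5 to 58.7 under ammonium limitation. Fatty acid degradation had -2.19 and -0.20, the TCA cycle -1.14 and 0.65, acetate uptake, glyoxylate shunt and gluconeogenesis -1.52 and 0.27, ATP synthase -0.41 (0.04 under TPM rescaling) and 0.49, and NADH dehydrogenase I -0.52 and 0.33. The Ntr list had -0.27 under glucose (0.17 under TPM rescaling) and -1.58 under ammonium limitation, where 39 of 42 members were lower and rutE went from 262 to 23.0 and rutB from 578 to 58.7. The RpoS list had 0.48 and -0.93, with gadA going from 171 to 1349 under glucose and from 5072 to 388 under ammonium limitation, and curli had 0.75 and -0.84. The iron uptake list had -0.03 (positive under FPKM as deposited, TPM and quantile normalization) and 0.65, and cirA went from 124 to 872 under ammonium limitation.

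Over the 3297 genes the growth-rate ratios under the 2 limitations, which share no library, had Pearson's r = 0.064 and Spearman's rho = 0.079, and among 2981 genes of at least 300 nt r was -0.048. At least 2-fold higher at 0.44 per h were 120 genes under glucose and 126 under ammonium limitation, 18 of them under both. At least 2-fold lower were 348 and 189, 35 of them under both, and 63 genes differed by at least 2-fold in opposite directions. Among the 2981 genes of at least 300 nt, 71 and 83 were higher (7 under both) and 290 and 132 lower (23 under both). Of these longer genes, 47 differed in opposite directions. The spread over genes (SD of the log2 contrast) was 1.32 for limitation, 0.888 for growth rate and 0.833 for their departure from additivity. Among genes of at least 300 nt it was 0.866, 0.482 and 0.505.

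**Figure D4:**
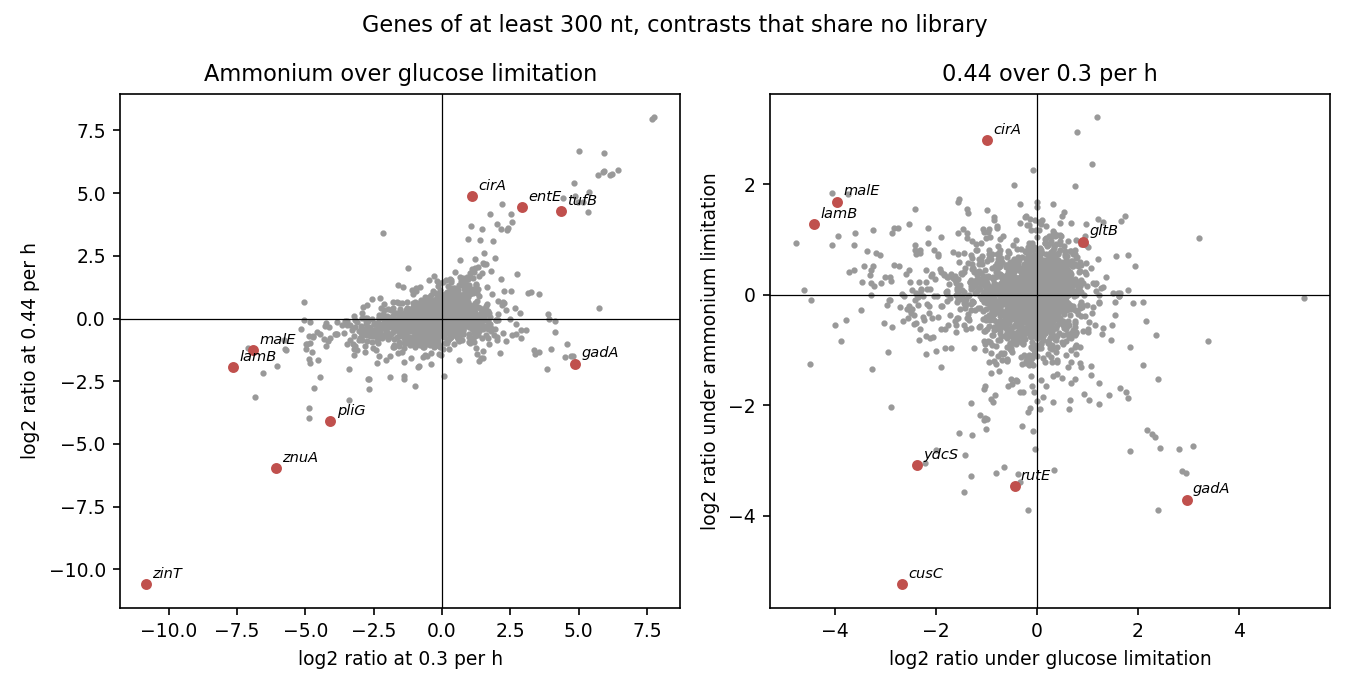
Log2 ratios of scaled FPKM + 1 for the genes of at least 300 nt, 1 point per gene, for ammonium over glucose limitation at 0.3 against 0.44 per h (left) and for 0.44 over 0.3 per h under glucose against ammonium limitation (right), with selected genes in red. Pearson's r across these 2981 genes is 0.538 on the left and -0.048 on the right.

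The difference of growth-rate effects between limitations has no residual degrees of freedom and no test. The 5 largest in each direction by the rule were short features with zeros, yabQ, a feature without a symbol, yaiZ, ybdZ and rttR on the side higher with rate under ammonium limitation and hokD, acrZ, yfgG, yhdV and hybG on the other. For example, hokD had 768 and 864 scaled FPKM under glucose limitation at 0.3 and 0.44 per h, had 3478 under ammonium limitation at 0.3 per h and is listed at 0 there at 0.44 per h. Among genes of at least 300 nt, a limit chosen after the data were seen, the 10 largest positive differences included malK, lamB, malE, the galactose-binding protein gene mglB and yjcH. The largest negative differences included gadA, gadB, gadC, hdeB and the multidrug efflux genes mdtE and mdtF. The growth-rate ratio of malK was 16.7-fold lower under glucose limitation and 3.58-fold higher under ammonium limitation, and that of gadB was 7.77-fold higher and 9.40-fold lower. The periplasmic chaperone gene hdeB had 1397 and 7064 under glucose limitation and 16436 and 2764 under ammonium limitation at 0.3 and 0.44 per h.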

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

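Gene lists are given here where their median lay outside the central 95% of matched random lists in opposite directions in a pair of contrasts that share no library. The lists were fixed before the data were examined, and this criterion was chosen after the medians were seen. Each value is the second median minus the first, on the log2 scale, and the difference was not tested, since each condition has 1 library.

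Between growth-rate effects, ammonium minus glucose limitation, the difference was 2.89 for carbon-source uptake genes (-2.46 and 0.43). It was 1.78 for the TCA cycle (-1.14 and 0.65), 0.89 for ATP synthase (-0.41 and 0.49) and 0.86 for NADH dehydrogenase I (-0.52 and 0.33). With the other sign, it was -1.40 for RpoS general stress genes (0.48 and -0.93) and -1.59 for curli (0.75 and -0.84). Between limitation effects, 0.44 minus 0.3 per h, the difference was -1.23 for Ntr genes (1.03 and -0.20) and -1.69 for RpoS general stress genes (1.21 and -0.48). For a single gene, this difference and the one between growth-rate effects are the same quantity. The 2 RpoS values are therefore not separate observations, and they differ only because medians were subtracted. Taken gene by gene, the median difference of the RpoS list was -1.36. The RpoS list holds genes listed at 0 in 1 library. Over its 29 members of at least 300 nt the medians were 1.43 and -0.32 for limitation and 0.59 and -0.85 for growth rate. Among the medians behind these 8 values, the ATP synthase median under glucose limitation turned positive (0.04) under TPM rescaling.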

How the results depend on the processing

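The restrictions by length and to non-repeated features, and robust variance estimation, were chosen after seeing the data. The 17 features that changed with limitation in limma became 13 to 24 under either pseudocount, either filter, FPKM as deposited, quantile normalization, no variance trend, robust estimation or without repeated features. Counts hide changes of membership. With no variance trend 12 of the 17 were shared, and pliG, tufB, ryhB, sibB and mgtS did not pass. Under quantile normalization 16 were shared, without ryhB. With the minimum of 50 scaled FPKM dinQ, yciX, ykgO and mgtS did not pass, and with the pseudocount of 10 sibB, mgtS and fnrS did not. On FPKM as deposited mgtS was lost, and under robust estimation sibB and mgtS. With growth rate left out of the model, which gives 2 residual degrees of freedom, the count was 35 (12 higher, 23 lower). Among genes of at least 300 nt it was 6 (zinT, znuA, pliG, tufB, insH4, insH9). Among genes of at least 300 nt without repeated features 3 were left (zinT, znuA, pliG). TPM rescaling gave 307 (154 higher, 153 lower) for limitation, all 17 among them, and 96 (41 higher, 55 lower) for growth rate, against 0. It shifted the median of all genes by 0.59 in the limitation contrast at 0.3 per h and by 0.15 at 0.44 per h, which adds the same departure from additivity to nearly every gene, and the prior degrees of freedom of the variance went from 1.95 to infinite. Leaving out 1 library at a time, which drops the other factor and assumes that the lone library varies like the pair, gave 0 to 48 for limitation. It was 44 without glucose at 0.3 per h, 48 without glucose at 0.44 per h, and 0 without either ammonium-limited library, with 248 (0.3 per h) and 237 (0.44 per h) at an unadjusted p under 0.05. For growth rate it was 0 in all 4. The correlation of growth-rate ratios was -0.048 among genes of at least 300 nt and -0.047 also without repeated features, and the spread of the departure from additivity was 0.505 and 0.504, where fewer short features with zeros enter. Shifts of the median of all genes over 0.1 were also 0.22 and 0.17 (limitation at 0.3 and 0.44 per h) for FPKM as deposited, 0.44 (growth rate under glucose limitation) for TPM, and 0.14 and 0.13 (limitation at 0.3 per h and growth rate under glucose limitation) for quantile normalization, and list medians move with them. Of 124 list medians, 13 changed sign with FPKM as deposited, 23 under TPM and 6 under quantile normalization. Those more than 2 standard errors over their members from 0 before the change were phosphate starvation at 0.44 per h with FPKM as deposited (0.0068) and, under TPM, Ntr genes (0.17) and ATP synthase (0.042) for growth rate under glucose limitation and cytochrome oxidases (0.26) and heat shock (0.35) for limitation at 0.3 per h. This standard error treats list members as independent, which members of an operon are not, so it served as a cutoff and not as a test. Without glucose at 0.3 per h, the growth-rate values of raiA (0.22) and nuoA (0.13) changed sign, and without ammonium at 0.3 per h the limitation value of cusC (-0.37), while leaving out each library in turn gave ranges of -2.89 to 0.22, -1.63 to 0.13 and -0.37 to 4.88. The cause was not tested.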

Other observations

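Other metal-related genes differed between the libraries, in groups chosen after their values were seen. The molybdate transporter genes modA, modB and modC had 1918, 461 and 199 scaled FPKM under glucose limitation at 0.3 per h, 668, 197 and 82.8 at 0.44 per h, and 54.9 to 65.3, 42.6 to 48.4 and 38.2 to 42.0 under ammonium limitation. The neighbouring modF differed little, at 245, 234, 255 and 286 in glucose at 0.3, glucose at 0.44, ammonium at 0.3 and ammonium at 0.44 per h. The copper efflux genes cusC, cusF and cusB were highest in ammonium limitation at 0.3 per h (152, 183 and 102) and had 1.06 to 12.1, 9.92 to 11.4 and 3.23 to 10.5 in the other 3 libraries. The copper genes cueO and copA went the other way, with 412 and 557 in glucose limitation at 0.3 per h against 157 and 213 in ammonium limitation. None of these genes passed the limma test for limitation (adjusted p from 0.20 for modA to 0.70 for modF).

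All tests in the following paragraphs were chosen after the results were seen.

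A first pattern is that 23 features are listed at 0 in both ammonium-limited libraries while above 10 FPKM in both glucose-limited ones. A technical candidate explanation is the longer cDNA fragments of the ammonium-limited libraries. All 23 (100%) were shorter than the smaller mean fragment of these libraries, 264.0 nt, against 6.82% of tested features. Among the 23, yjeT, ymcE and ydhI lie below the expression filter and are not tested features. A lower transcript level under ammonium limitation would not need short genes, and 0 of 2981 tested genes of at least 300 nt show the pattern. That count cannot decide the question, because a longer gene hardly reaches an exact 0 whatever its change. For the same reason the 100% was largely set by the pattern itself and cannot decide the question either. The 651 nt gene zinT fell by 10.72 log2 units and still had 13 and 16 fragments under ammonium limitation. Short length alone does not give 0, since 13 and 15 of the 38 tested features under 150 nt have values in the ammonium-limited libraries (30 in each glucose-limited one), ryhB and b1016 among them. For a single short feature, such as dinQ or sra, length and a lower transcript level under ammonium limitation cannot be told apart, because no value here separates them.

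A second pattern is a low tufB (522 and 641 scaled FPKM) and insertion-sequence copies listed at 0 in the glucose-limited libraries. Fragments that match several copies may have been assigned differently in the glucose and ammonium files, and for the tuf genes the values go with this, since tufB alone had a mean log2 ratio of 4.33 while the sum of tufA and tufB had 0.081. The sum over 11 insH copies had a mean log2 ratio of -0.70, from 5026 to 1921 scaled FPKM at 0.3 per h and from 2286 to 2267 at 0.44 per h, which leaves assignment open for that family. The mean log2 ratios of the sums were 1.57 for insC, 0.50 for insE and 0.07 for insI, and the insD sum went from 0.0019 and 4.49 to 40.8 and 31.9, which a shift among the 7 insD copies alone would not give, and features without a symbol were not summed. No biological explanation was tested for this pattern, and a change of tufB expression between limitations stays open.

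The last pattern is the low level of zinT and znuA, and without passing the limma test of znuB and znuC, in both ammonium-limited libraries, a group put together after the values were seen. The genes zinT, znuA, znuB and znuC are longer than 600 nt, and the smallest of their absolute log2 changes was 2.55. The 95th percentile for genes of 600 to 1000 nt was 1.41, so most genes of this length changed far less. The 4 genes were grouped for their large changes, so passing that percentile was close to fixed in advance. Genes of 600 to 1000 nt as a whole were not chosen by their change, and a fragment-length effect shared by genes of this length would show in them too. Their small changes therefore argue against such a shared effect as the cause for these 4 genes. Scaling does not remove the low level, because the log2 ratio closest to 0 over these 4 genes, both growth rates and 4 scalings was -1.998. A hypothesis is that more zinc was available to the ammonium-limited cultures, which may also raise the zinc exporter gene zntA, and its log2 ratio was 1.11 at 0.3 per h and 1.98 at 0.44 per h (113 and 100 fragments under glucose, 375 and 529 under ammonium limitation), and zntA did not pass the limma test for limitation (adjusted p = 0.46). Trace metals in the medium are not given in the sources used here, so zinc supply, the limitation itself and a preparation batch that followed limitation stay open.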
